A study of Homo sapiens with 40 samples.

How the data were processed

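The series has 40 samples: 19 pA-DamID libraries of hTERT RPE-1 cells, 18 ChIP-seq libraries of K562 clone #5 and 3 pooled inputs, which were not used here. In RPE-1 all libraries were from cells given the vehicle DMSO, so these data hold no drug comparison in that line. Replicates r8 and r9 were each joined by the authors from 3 sequencing runs, 2 NovaSeq and 1 HiSeq. The main fit has no term for this, and alternatives took r8 and r9 or r4 to r7 alone. Below, each of these sets is called a batch, though the labels do not name batches and do not state the runs of r4 to r7. Among r4 to r7, H3K27me3 had r4 and r5 and H3K9me2 had r6 and r7, so they share no replicate number there. In K562 each mark (H3K27ac, H3K27me3) had 3 libraries per treatment (DMSO, 100 nM PCI-24781, 10 µM tubastatin A, 16 h).

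The pA-DamID files hold raw read counts per GATC fragment on hg38, made by the authors with cutadapt 1.11 and BWA 0.7.17 and deposited without normalization; filters are not stated. The ChIP files are MACS2 peak lists on GRCh38, called by the authors per library after alignment with BWA 0.5.10, as narrow peaks for H3K27ac and broad peaks for H3K27me3. In these deposited lists the fold enrichment of a peak over background, its -log10 p and -log10 q and its integer score (10 times the -log10 q, cut to a whole number) are the authors' MACS2 values, and the control used is not stated. The lowest -log10 q was about 2 in the H3K27ac lists and about 1 in the H3K27me3 lists, as the values themselves show. Folds and scores were not compared between lists. The -log10 q served to rank peaks within a list and to set the stricter threshold. The read depth of the ChIP libraries is not in the files.

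Counts of the 7127409 fragments on chromosomes 1 to 22 and X were summed by fragment midpoint over 19309 protein-coding genes, each extended by 5 kb on both sides, and over 50 kb bins. The gene table gives no strand, so a transcription start could not be placed, and what the design called promoters were windows of 1000 bp to each side of both annotated gene ends. A gene counted as marked where peaks of a list covered at least 200 bp of such a window. The first gene table placed 22 further genes by coordinates of alternate sequences; they were removed after results had been seen, when one of them appeared among the named genes. Of the symbols in the gene lists, 1 had no match in the table.

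Libraries were compared with edgeR 4.0.16 in R 4.3.3: TMM factors, filterByExpr, a quasi-likelihood fit of all 19 libraries with 1 level per group, F-tests and Benjamini-Hochberg adjustment, called at an adjusted p under 0.05. A standard error is the absolute log2 fold change divided by the square root of F. The 3 marks were each compared with Dam and with each other, 6 comparisons of genes, and with Dam in bins. The smallest adjusted p-values assume that libraries, not cultures, are the replicates. Set tests used camera in limma 3.58.1 with a preset correlation of 0.01 on 22 lists, adjusted over the 22 lists of each comparison, and again with an estimated correlation; an adjustment over all 132 tests was added after the results had been seen. The lists were HOX genes, zinc finger genes of chromosome 19, olfactory receptors, clustered protocadherins, keratins, ribosomal protein genes, replication histones, developmental transcription factors, long neural genes, REST-type neuronal genes, erythroid and megakaryocytic genes, deacetylase-inhibitor response genes, deacetylases and acetyltransferases, double-strand break repair, Polycomb and H3K9 machinery, mesenchymal and epithelial genes, differentiated pigment epithelium, lymphoid, hepatocyte, germline, housekeeping and cell-cycle genes. Data were simulated from each comparison's own fit, with 200 genes changed, as many up as down. Far more genes were called in the real comparisons, so an error of scaling could not show in this test. The pipeline recovered 37.5% to 82.8% of genes changed by 1 on the log2 scale and 95% to 99% of those changed by 2. It made 4 to 10 false calls, and 21 for H3K9me2 against H3K9me3; the limit set for false calls in the test was loosened after that value was seen.

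Peak lists were compared in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, with the list as the unit. Means over 3 lists were tested by exact permutation of the F statistic over all partitions of the 9 lists (smallest p 0.00357), and pairs of treatments by exact two-sided permutation, whose smallest p is 0.10. Adjustment was over the 16 measures computed, and over 44 list tests. Regions are unions of peaks over the 9 lists of a mark. A region or gene was gained when all 3 treated lists and no control list called it, and lost in the reverse case; such a call cannot pass a test at 0.05 for a single feature, so counts were set beside the 9 other splits of the same 6 lists. Base-pair Jaccard indices between lists were tested by an exact permutational analysis of distances. Part of its R² arises without any treatment effect, so the permutation p is the test and not the share. H3K27me3 regions covered by all 3 DMSO lists (93.03 Mb) served as context for H3K27ac alone. The overlap of the changes of both drugs, which share their DMSO lists, was set against 100 simulations that shuffled each region's calls over the 9 lists; these were added after the overlaps had been seen.

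Named genes followed a fixed rule. For pA-DamID these are the 8 genes per direction with the largest log2 fold change among called genes whose groups' libraries did not overlap, keeping the foremost of any within 1 Mb, and 2 to 4 members with the largest or smallest change per list. For ChIP they are up to 10 gained and 10 lost genes ranked by the lowest percentile of their -log10 q over the lists that hold them, and list members gained or lost. A gene that met this rule is not reported here. Alternatives were DESeq2 1.42.0, RLE factors, library totals, no low-count filter, a block on the replicate number, only the 2 groups compared, each batch alone, 100 kb bins, each library left out, peaks with a -log10 q of at least 5, the same number of peaks in each list (39121 for H3K27ac, 124682 for H3K27me3), regions and windows at least 50% covered, and permutation within the replicate number. Windows of 5 kb around both gene ends were added after the files were seen, in place of a planned window around the transcription start.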

Results

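Repressive histone marks were mapped in hTERT RPE-1, an immortalised human retinal pigment epithelial line, and the response of histone marks to 2 deacetylase inhibitors was mapped in K562 clone #5, of a human erythroleukaemia line. The RPE-1 maps came from pA-DamID, in which an antibody brings a fusion of protein A and the Dam methylase to a histone mark and the enzyme tags GATC sequences nearby. All 19 RPE-1 libraries were from vehicle-treated cells: 4 for H3K27me3, the Polycomb mark, 4 for H3K9me2 and 5 for H3K9me3, marks of heterochromatin, and 6 with Dam alone as the background. Counts per library ran from 3514047 to 10069072 for H3K27me3, from 3054754 to 9402161 for H3K9me2, from 2668526 to 9406275 for H3K9me3 and from 3128470 to 9602625 for Dam, and each library had counts in 20.7% to 47.7% of the 7127409 GATC fragments. Across 50 kb bins, libraries of the same group correlated at 0.85 to 0.97 for H3K27me3, 0.94 to 0.98 for H3K9me2, 0.73 to 0.97 for H3K9me3 and 0.88 to 0.98 for Dam; bins are not independent replicates. The K562 data were 18 ChIP-seq peak lists, 3 for each of H3K27ac and H3K27me3 after 16 h with DMSO, 100 nM PCI-24781 (abexinostat, an inhibitor of many histone deacetylases) or 10 µM tubastatin A (an HDAC6 inhibitor). Both drugs are hydroxamates and were used at different doses. The peak lists carry no read counts, so the ChIP depth is unknown. All p-values measure the spread between these libraries, since the labels do not say whether replicates were separate cultures.

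H3K27me3 was compared with Dam alone to see which genes lie in Polycomb chromatin in RPE-1 cells. Many genes of other lineages carried it, above all keratins of hair and skin, lymphoid, hepatocyte and germline genes, blood regulators and neuronal genes, though no list call for this mark held with an estimated correlation between genes. So did 38 of 66 listed transcription factors of development, while HOX genes were split. Genes that every dividing cell uses, for ribosomal proteins, DNA repair and acetyltransferases, lay below the background, as did zinc finger genes of chromosome 19. Values below Dam cannot tell a low mark from a high Dam signal. The highest gene was TRH, the thyrotropin-releasing hormone precursor (chromosome 3, 129974720 to 129977935), at a log2 fold change of 3.79 ± 0.24 (SE, 4 against 6 libraries; adjusted p = 4.28e-12). POU4F3, a factor of inner-ear hair cells (chromosome 5, 146338839 to 146341728), followed at 3.61 ± 0.20 (adjusted p = 9.78e-13). The other genes named by the same rule were IGFL3 (3.48), the cilium gene UBXN10 (3.46), the eye-field factor SIX6 (3.45, with the Dam r6 library apart from the other 5), the neuropeptide gene CARTPT (3.39), NKX6-3 (3.33) and FOXL3 (3.30). The lowest genes outside segmental duplications were COMMD2 (-2.51 ± 0.60), the olfactory receptor OR5T1 (-2.44), the bitter-taste receptor TAS2R13 (-2.40), TMEM106A (-2.35) and PROCA1 (-2.31). For TMEM106A the Dam r4 library and for PROCA1 the H3K27me3 r4 library stood apart from the rest of its group. NOTCH2NLB (-3.03), NBPF10 (-2.89) and GTF2H2C (-2.83) were lower still, in families of near-identical copies and near the floor in H3K27me3. In all, 13694 of 18935 genes passed an adjusted p of 0.05 (edgeR), 5927 higher and 7767 lower than Dam. With library totals in place of TMM scaling, the median log2 fold change shifted by -0.71 and the higher share fell from 43.3% to 25.5% of 15925 called genes, and in a fit of the 2 groups alone it shifted by 0.14, with 49.6% of 12457 higher.

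Among the gene lists fixed before the data were examined, 31 of 55 keratin genes were higher and 9 lower than Dam, and 31 and 9 adjusted over the list alone, with a median log2 fold change of 1.39, or 29 higher, 22 lower and a median of 0.68 under library totals (adjusted p = 3.18e-07, camera; adjusted p = 0.157 with an estimated correlation). KRT71 reached 3.15 ± 0.20 and KRT74 3.12, both of the hair follicle, while KRT8 of simple epithelia lay at -0.97 ± 0.16. Of 66 developmental transcription factors, 38 were higher and 8 lower, the same adjusted over the list alone, with OLIG2 at 3.25 ± 0.17 and TWIST1 at -1.41 (median 0.89, or 29 higher, 26 lower and a median of 0.16 under library totals; adjusted p = 8.83e-05; adjusted p = 0.365 with an estimated correlation). REST-type neuronal genes had 22 of 30 higher (22 adjusted over the list alone) with a median of 1.53 and L1CAM at 2.76 ± 0.16, and erythroid and megakaryocytic genes 22 of 36 (22 adjusted over the list alone) with a median of 1.02 and TAL1 at 2.79 ± 0.22 (adjusted p = 0.000155 and 0.000993; adjusted p = 0.0823 for both with an estimated correlation). Lymphoid genes had a median of 1.60, with 13 of 20 higher and PAX5 at 2.80 ± 0.19, hepatocyte genes one of 1.57, with 14 of 18 higher and CYP3A4 at 2.51 ± 0.22, and germline genes one of 1.71, with 13 of 20 higher and TDRD1 at 2.74 ± 0.26; each count was the same adjusted over the list alone. Their adjusted p-values were 8.87e-05, 0.000993 and 0.000414, and with an estimated correlation adjusted p = 0.0823, 0.365 and 0.36. Under library totals REST-type genes had 18 higher and 8 lower (median 0.76), erythroid and megakaryocytic genes 16 and 9 (0.37), lymphoid genes 11 and 6 (0.87), hepatocyte genes 10 and 1 (0.84) and germline genes 13 and 5 (0.93). Lists below Dam lay lower still there, with repair genes at a median of -1.68, zinc finger genes at -1.36 and ribosomal protein genes at -1.44. Of 32 double-strand break repair genes 27 were lower and 2 higher, the same adjusted over the list alone, with BRCA1 at -1.65 ± 0.25 and RBBP8 at -1.68 ± 0.19 (median -0.97, adjusted p = 0.000388; adjusted p = 0.145 with an estimated correlation). Deacetylases and acetyltransferases had 16 of 22 lower (16 adjusted over the list alone) with EP300 at -1.45 ± 0.14, though HDAC8 (0.43) and HDAC11 (0.52) lay higher and turned lower under library totals (-0.31 and -0.20). The list's median was -0.94 (adjusted p = 0.00526; adjusted p = 0.145 with an estimated correlation). Chromosome 19 zinc finger genes had 142 of 240 lower and 9 higher (137 and 9 adjusted over the list alone; median -0.65; adjusted p = 0.000388; adjusted p = 0.479 with an estimated correlation). Ribosomal protein genes had 49 of 83 lower (49 adjusted over the list alone; median -0.75, adjusted p = 0.00134; adjusted p = 0.479 with an estimated correlation), and the 20 housekeeping genes 15 lower (17 adjusted over the list alone; median -0.84, adjusted p = 0.0205; adjusted p = 0.41 with an estimated correlation). Polycomb and H3K9 machinery lay lower at SETDB1 (-1.81 ± 0.21), which writes H3K9me3, and higher at the Polycomb genes CBX8 (2.36 ± 0.19) and CBX2 (1.97 ± 0.15), with a median of -0.78 that did not pass (adjusted p = 0.0889; adjusted p = 0.0371 with the replicate block). Mesenchymal and epithelial genes, listed as expressed in RPE-1 from general knowledge, had 18 of 30 lower (18 adjusted over the list alone) with FN1 at -1.63 ± 0.21 (median -0.77, adjusted p = 0.0239; adjusted p = 0.444 with an estimated correlation). The list for the differentiated retinal pigment epithelium was split, with its member CRX, a photoreceptor factor, at 2.55 ± 0.17 and MERTK at -1.13 ± 0.15. Its median was 0.20, or -0.57 under library totals (adjusted p = 0.202, camera). HOX genes had 15 of 39 higher and 8 lower (14 and 6 adjusted over the list alone), from HOXC13 at 2.39 ± 0.19 to HOXB4 at -1.18, and a median of 0.39 that turned to -0.32 under library totals (adjusted p = 0.207).

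**Figure D1:**
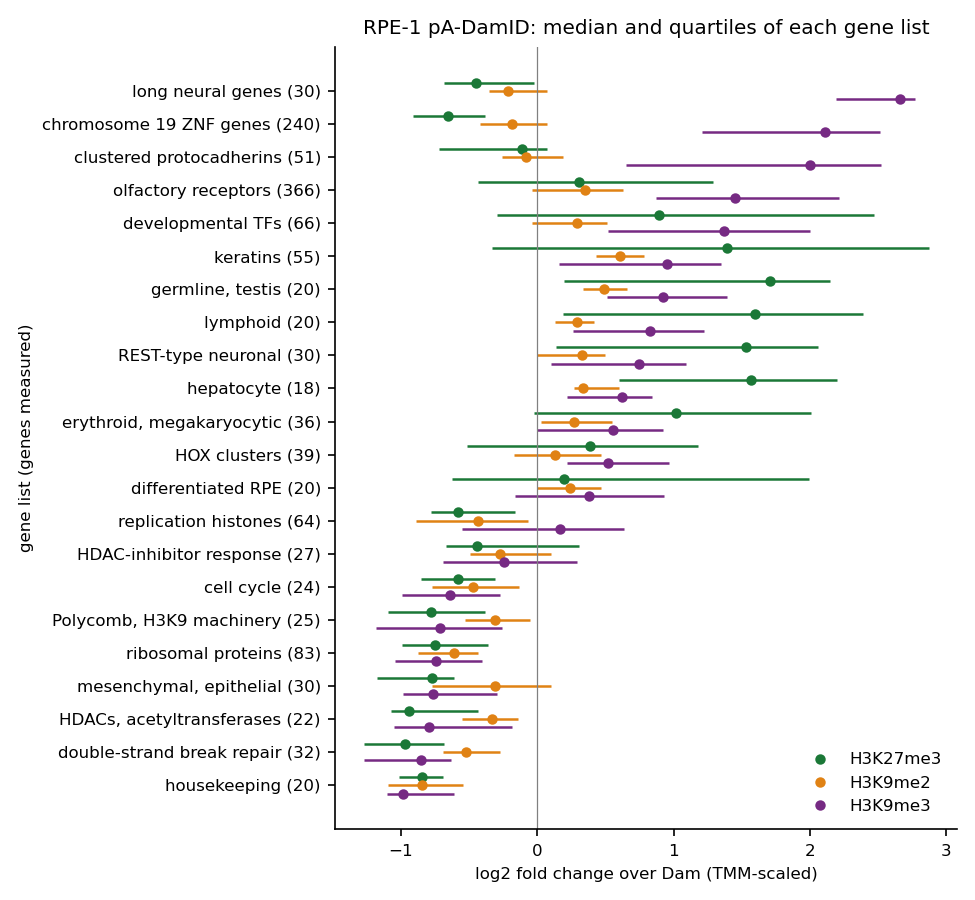
Median (point) and quartiles (line) of the log2 fold change over Dam for each gene list, by antibody, in RPE-1 cells with TMM scaling; the number of genes measured is in brackets. Long neural genes sit at 2.66 for H3K9me3 against -0.45 for H3K27me3 and keratins at 1.39 for H3K27me3; under library totals the medians of HOX, differentiated pigment epithelium and olfactory genes turn negative for H3K27me3, those of HOX genes for H3K9me2, and those of HOX, replication histone, neuronal, erythroid, pigment epithelium, lymphoid, hepatocyte and germline genes for H3K9me3.

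H3K9me3 was compared with Dam alone to map constitutive heterochromatin. It covered zinc finger genes, clustered protocadherins and olfactory receptors, which are repeated gene families, and very long neuronal genes. Protocadherins that share a gene end, such as PCDHA7 and PCDHA8, reuse the same fragments, so the counts of that list are not of separate genes. DNA repair, cell-cycle and housekeeping genes lay below the background. Repair and housekeeping genes did so for H3K27me3 and H3K9me2 as well, and the comparisons of all 3 marks use the same Dam libraries. The low values are thus not particular to H3K9me3, and a low mark cannot be told from a high Dam signal there. Of the list calls for H3K9me3 only those of zinc finger and repair genes held with an estimated correlation, and adjusted over all list tests only that of repair genes. ZFP90, a zinc finger gene (chromosome 16, 68533479 to 68576506), was at 3.16 ± 0.20 (SE, 5 against 6 libraries; adjusted p = 1.04e-10), with the Dam r7 library apart from the others, and ZNF732 (chromosome 4, 270675 to 305474) at 3.19 ± 0.24 (adjusted p = 6.68e-10). ZNF501 (3.11, Dam r7 again apart), ZNF300 (3.11), the keratin-associated gene KRTAP19-2 (3.16), the homeobox gene ANHX (3.13) and the sperm-tail gene FSIP2 (3.10) followed, and FAM90A10, of a duplicated family and near the floor in Dam, was highest at 3.75. The lowest genes were GPR18 (-2.66 ± 0.57), RBM15B (-2.43 ± 0.40), NPFF (-2.34), MEA1 (-2.32, with Dam r5 apart), the glutathione peroxidase gene GPX2 (-2.25), the centrosomal gene CEP95 (-2.24), the spindle gene SPAG5 (-2.22) and the RNA helicase gene DDX55 (-2.22). For SPAG5 the H3K9me3 r4 library stood apart. Of 18935 genes, 13008 passed (edgeR), 6322 higher and 6686 lower. Under library totals the median shifted by -0.92 and 14.7% of 14979 called genes were higher, against 48.6%.

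Of the 240 zinc finger genes of chromosome 19, 204 were higher and 9 lower in H3K9me3 (205 and 10 adjusted over the list alone), with ZNF426 at 3.07 ± 0.19 and a median of 2.11, or 164 higher, 34 lower and a median of 1.13 under library totals (adjusted p = 1.21e-51, camera; adjusted p = 0.0176 with an estimated correlation, or 0.0529 adjusted over all 132 list tests). All 30 long neural genes were higher, and all 30 adjusted over the list alone, with the receptor gene LRP1B at 3.03 ± 0.37 and the adhesion gene CNTN6 at 3.01 ± 0.37 (median 2.66, adjusted p = 2.52e-12; adjusted p = 0.249 with an estimated correlation); IL1RAPL1 (0.92) and GPC6 (1.05) turned to -0.12 and -0.01 under library totals. Clustered protocadherins had 41 of 51 higher and none lower (41 adjusted over the list alone), with PCDHA2 at 2.59 ± 0.26 (median 2.00, or 28 higher, 11 lower and a median of 0.99 under library totals; adjusted p = 1.99e-12; adjusted p = 0.197 with an estimated correlation). Olfactory receptors had 302 of 366 higher and none lower (306 adjusted over the list alone; median 1.45, or 174 higher, 30 lower and a median of 0.49 under library totals; adjusted p = 1.82e-18; adjusted p = 0.197 with an estimated correlation). Developmental transcription factors had 50 of 66 higher (50 adjusted over the list alone), with LHX8 at 2.82 ± 0.27 and GATA6 at -0.70 (median 1.37, or 32 higher, 15 lower and a median of 0.42 under library totals; adjusted p = 4.13e-12; adjusted p = 0.119 with an estimated correlation). Keratins had 38 of 55 higher (38 adjusted over the list alone), with KRT26 at 2.13 ± 0.14 and KRT18 at -1.27 ± 0.24 (median 0.95, or 15 higher, 17 lower and a median of 0.02 under library totals; adjusted p = 4.35e-06; adjusted p = 0.155 with an estimated correlation). HOX genes had 21 of 39 higher (21 adjusted over the list alone), with HOXA7 at 2.15 ± 0.20 and a median of 0.52 that turned to -0.41 under library totals (adjusted p = 0.0139; adjusted p = 0.27 with an estimated correlation, and adjusted p = 0.0681 with the replicate block). Double-strand break repair genes had 27 of 32 lower and none higher (27 adjusted over the list alone), with DNA2 at -1.65 ± 0.20, RBBP8 at -1.57 ± 0.18 and a median of -0.85 (adjusted p = 8.57e-07; adjusted p = 0.0056 with an estimated correlation). Under library totals the medians of long neural, repair, housekeeping and cell-cycle genes were 1.54, -1.76, -1.89 and -1.55. Housekeeping genes had 15 of 20 lower and 1 higher (15 and 2 adjusted over the list alone), with a median of -0.98 (adjusted p = 0.0111; adjusted p = 0.27 with an estimated correlation). Cell-cycle genes had 14 of 24 lower (14 adjusted over the list alone), among them CCNA2 (-1.91) and TOP2A (-1.48), with a median of -0.64 (adjusted p = 0.0111; adjusted p = 0.192 with an estimated correlation). Replication histone genes had 18 of 64 higher and 8 lower (16 and 6 adjusted over the list alone), and their median of 0.17 turned to -0.73 under library totals (adjusted p = 0.476). With p-values adjusted over the 22 lists of each of the 6 comparisons, 74 of 132 list tests passed 0.05 with the preset correlation (camera) and 4 with an estimated one: zinc finger genes in all 3 comparisons of H3K9me3, and the repair genes here. Adjusted over all 132 tests, 75 and 3 passed. The zinc finger genes against Dam were not among the 3.

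H3K9me2 was compared with Dam alone for the other methylation state of lysine 9. Its gains were smaller. Among called 50 kb bins, the higher ones had a median log2 fold change of 0.54, against 1.51 for H3K27me3 and 1.42 for H3K9me3. Losses were closer in size, with medians of -0.84 against -0.91 and -1.1. Most keratins lay above the background, and many ribosomal protein, housekeeping, cell-cycle and repair genes below it. Housekeeping and repair genes lay below Dam for the other marks too, against the same Dam libraries, so this is not particular to H3K9me2. No list call for this mark held with an estimated correlation. CAPZA3, an actin-capping gene of the testis (chromosome 12, 18738119 to 18739188), was at 1.52 ± 0.30 (SE, 4 against 6 libraries; adjusted p = 0.00252) and the acetyltransferase gene NAT8 (chromosome 2, 73640723 to 73642422) at 1.49 ± 0.26 (adjusted p = 0.00151). The olfactory receptor OR51B6 (1.26), MAGEA3 (1.24), the testis gene TAF1L (1.23) and KRTAP3-1 (1.22) followed, with FAM90A10 (1.37) and RGPD1 (1.33) of duplicated families. CEP95 (chromosome 17, 64506762 to 64537946) was lowest at -2.00 ± 0.25 (adjusted p = 0.000183), followed by HCFC1R1 (-1.78), GPR18 (-1.78), nucleostemin GNL3 (-1.72), CCDC85B (-1.70), the translation factor EIF4A1 (-1.59), the ESCRT gene CHMP5 (-1.58) and MAB21L2 (-1.58). For HCFC1R1, CCDC85B and EIF4A1 the Dam r7 library lay far above the other 5 Dam libraries. Keratins had 36 of 55 higher and none lower (39 adjusted over the list alone), with KRT38 at 1.08 ± 0.20 (median 0.61, or 16 higher and a median of 0.38 under library totals; adjusted p = 2.01e-13; adjusted p = 0.0664 with an estimated correlation). Germline genes had 9 of 20 higher (13 adjusted over the list alone; median 0.49, adjusted p = 3.39e-05; adjusted p = 0.174 with an estimated correlation), and olfactory receptors 58 of 366 (46 adjusted over the list alone; median 0.35, adjusted p = 7.99e-06; adjusted p = 0.553 with an estimated correlation). Under library totals 3 germline genes were higher (median 0.27), and 27 olfactory receptors were higher and 10 lower (median 0.13). Ribosomal protein genes had 36 of 83 lower (45 adjusted over the list alone), with RPL4 at -1.33 ± 0.30 (median -0.61, adjusted p = 1.87e-11; adjusted p = 0.153 with an estimated correlation). Housekeeping genes had 13 of 20 lower (16 adjusted over the list alone), with HSPA8 at -1.51 ± 0.39 (median -0.84, adjusted p = 2.05e-06; adjusted p = 0.127 with an estimated correlation). Repair genes had 15 of 32 lower (17 adjusted over the list alone), with PRKDC at -0.90 ± 0.14 (median -0.52, adjusted p = 2.27e-06; adjusted p = 0.0664 with an estimated correlation). Genes that respond to deacetylase inhibitors had 5 of 27 lower and 2 higher (5 and 2 adjusted over the list alone), with MT2A at -1.43 and a median of -0.27 that did not pass (adjusted p = 0.359). Over all genes 4987 of 18935 passed (edgeR), 2476 higher and 2511 lower. Same-numbered H3K9me2 and Dam libraries correlated at 0.34 to 0.57 across genes after group means were removed, and with the replicate number as a block 9693 passed, 4782 higher and 4911 lower. The r8 and r9 libraries alone gave 8404, and r4 to r7 alone gave 0, with 5258 of 18779 genes at an unadjusted p under 0.05 (edgeR, the only tool run on those libraries). Without H3K9me2 r6, r7 or r8 the count fell to 2565, 3059 or 3272. Under library totals the median shifted by -0.22 and 21% of 4007 called genes were higher, against 49.6%.

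H3K9me3 was compared with H3K27me3 to separate the 2 repressive states. Zinc finger, protocadherin and long neural genes leaned to H3K9me3, and lymphoid, hepatocyte and, less clearly, erythroid and keratin genes to H3K27me3. Of these list calls only that of the zinc finger genes held with an estimated correlation. Protocadherins that share a gene end again count the same fragments more than once. GABRA6, a GABA receptor subunit gene (4.32 ± 0.47), DDI1 (4.40 ± 0.35), ZNF732 (4.30 ± 0.31), the receptor genes OR5T1 (4.58), OR4K2 (4.41) and VN1R2 (4.37), KRTAP21-3 (4.45) and POTEH (4.29) were the highest (5 against 4 libraries). In H3K27me3 OR5T1, OR4K2, POTEH, KRTAP21-3 and VN1R2 lay near the floor, so the size of these folds is uncertain. So it is for COMMD2, OR5T1 and TAS2R13 in H3K27me3 against Dam and for GPR18, RBM15B, NPFF and GPX2 in H3K9me3 against Dam. The same holds for GPR18 and FAM90A10 in H3K9me2 against Dam, and for COMMD2 in both comparisons of H3K9me2 with a trimethylated mark. IL25 (-2.50 ± 0.28), the histamine receptor gene HRH3 (-2.33), EQTN (-2.33), the metallothionein gene MT1G (-2.25) and the interferon gene IFNA4 (-2.22, with H3K27me3 r5 apart) were the lowest, with TBC1D3B (-3.02), DEFB104A (-3.01, with H3K9me3 r4 apart) and GOLGA6C (-2.24) of duplicated families, the first 2 of these near the floor in H3K9me3. Zinc finger genes of chromosome 19 had 220 of 240 higher in H3K9me3 (221 adjusted over the list alone; median 2.65, adjusted p = 3.26e-78, and adjusted p = 0.00613 with an estimated correlation). All 51 clustered protocadherins (51 adjusted over the list alone; median 1.57, adjusted p = 8.2e-19) and all 30 long neural genes (30 adjusted over the list alone; median 3.13, adjusted p = 1.34e-16) were higher too, with adjusted p = 0.382 and adjusted p = 0.497 with an estimated correlation. Hepatocyte genes had 12 of 18 lower (median -1.10, adjusted p = 0.0131) and lymphoid genes 14 of 20 (median -1.11, adjusted p = 0.0295), with adjusted p = 0.686 and adjusted p = 0.534 with an estimated correlation. Erythroid genes had 18 of 36 lower and 3 higher (median -0.48, adjusted p = 0.0264; adjusted p = 0.497 with an estimated correlation). Keratins had 28 of 55 lower and 11 higher (median -0.52, adjusted p = 0.0149; adjusted p = 0.686 with an estimated correlation). In all 9888 of 18935 genes passed (edgeR), 4450 higher and 5438 lower in H3K9me3. Under library totals the median shifted by -0.21 and 34.0% of 9462 called genes were higher, against 45.0%, and r4 to r7 alone gave 6341 against 12637 from r8 and r9.

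H3K9me2 was set against both trimethylated marks to ask where the dimethylated state differs. Against H3K27me3 its lowest named genes were the neuronal factor POU3F2 (-3.56 ± 0.39), the synaptic gene ARC (-3.57 ± 0.35), the insulin gene INS (-3.28 ± 0.34, with H3K9me2 r7 apart), UNCX (-3.38), PRSS56 (-3.33), TP53I11 (-3.28), BHLHE23 (-3.20) and DLX3 (-3.18). Its highest genes there were COMMD2 (2.91), PRPS1L1 (2.89), CAPZA3 (2.53), the succinate receptor gene SUCNR1 (2.51 ± 0.30, with H3K27me3 r5 apart), RGS18 (2.46), POU5F2 (2.43), HUS1B (2.42) and the cytokine gene IL1A (2.41 ± 0.35). Mean log2 CPM was low in H3K9me2 for ARC (0.91), POU3F2 (0.83) and INS (0.70). In H3K27me3 it was low for CAPZA3 (0.37), HUS1B (0.55) and PRPS1L1 (0.60). The size of these folds is uncertain too. REST-type neuronal genes had 21 of 30 lower (21 adjusted over the list alone; median -1.23, or 19 lower, 6 higher and a median of -0.70 under library totals; adjusted p = 0.000844; adjusted p = 0.139 with an estimated correlation). Lymphoid genes had 13 of 20 (median -1.30, or 11 lower, 4 higher and a median of -0.79 under library totals; adjusted p = 0.000707; adjusted p = 0.139 with an estimated correlation). In that comparison 10527 of 18935 genes passed (edgeR), 5164 higher and 5363 lower, and under library totals 12481 with 70.4% higher and a shift of 0.50. Batches gave 13074 (r8 and r9) and 6955 (r4 to r7). Against H3K9me3, the zinc finger genes ZNF345 (-4.02 ± 0.29), ZNF732 (-4.02), ZNF891 (-4.01, with H3K9me2 r7 apart), ZNF300 (-3.94), ZNF716 (-3.90) and ZNF208 (-3.76) were lowest, with KRTAP22-2 (-4.88) and OR4A16 (-3.87), both near the floor in H3K9me2. COMMD2 (2.75), the cytokine gene IL23A (1.98 ± 0.29), the proton-pump gene ATP6V0B (1.79), C10orf62 (1.67), CCDC28B (1.67, with H3K9me2 r8 apart), MSS51 (1.66), UTP15 (1.63) and SPDYE3 (1.62) were highest. Zinc finger genes of chromosome 19 had 203 of 240 lower and 1 higher (203 and 2 adjusted over the list alone; median -2.13, or 174 lower, 19 higher and a median of -1.37 under library totals; adjusted p = 2.3e-93, and adjusted p = 0.00146 with an estimated correlation). Repair genes had 13 of 32 higher (14 adjusted over the list alone; median 0.44, or 30 higher and a median of 1.13 under library totals; adjusted p = 0.00109; adjusted p = 0.171 with an estimated correlation). Here 7427 of 18935 genes passed (edgeR), 3418 higher and 4009 lower, while library totals gave 13008 with 87.7% higher and a shift of 0.71. Batches gave 8799 (r8 and r9) and 4712 (r4 to r7).

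Along the genome in 50 kb bins, H3K9me3 lay in regions poor in genes, and it had more megabase domains than H3K27me3 although most of its domains were short. Of 56521 bins, 20706 were higher in H3K9me3 than in Dam and 21206 lower, 19070 and 20750 for H3K27me3, and 5512 and 6092 for H3K9me2 (edgeR). Of the higher H3K9me3 bins 66.2% held no gene, against 41.5% of all bins, 38.9% of the H3K27me3 ones and 56.6% of the H3K9me2 ones. Unbroken runs of higher H3K9me3 bins numbered 2993, with a median of 100 kb, of which 290 reached 1 Mb. The longest ran for 8.5 Mb on chromosome 5 (21550001 to 30050000, 4 genes), followed by 7.5 Mb on chromosome 21 (17850001 to 25350000, 3 genes). H3K27me3 gave 4637 runs with a median of 150 kb and 41 of at least 1 Mb. Its longest was 4.35 Mb on chromosome X (109150001 to 113500000, 20 genes), and the densest in genes among the 8 longest was 1.8 Mb on chromosome 19 (50050001 to 51850000, 62 genes). The longest H3K9me2 run was 0.65 Mb on chromosome 9 (107750001 to 108400000, no gene). More than 2-fold above Dam lay 14602 bins for H3K9me3, 13888 for H3K27me3 and 6 for H3K9me2. More than 2-fold below it lay 11933, 7872 and 1602. The direction of bins moved with scaling. For H3K27me3, library totals shifted the median by -0.83 with 24.7% of called bins higher against 47.9%, dropping the low-count filter by -0.46 with 32.3% higher, and leaving out Dam r4 by -0.46 with 32.3% higher. The r4 to r7 libraries gave 59.5% of 27754 called bins higher, and r8 and r9 35.6% of 47154. For H3K9me2, dropping the filter shifted it by -0.21 with 5.7% higher against 47.5%, as did leaving out Dam r4 (-0.21, 4.7%) or H3K9me2 r7 (-0.19, 3.1%). For H3K9me3, RLE size factors shifted it by 0.19 with 57.3% higher against 49.4%. The replicate block gave 23689 H3K9me2 bins, 10577 higher and 13112 lower. The r8 and r9 libraries gave 22890 with 8.8% higher (shift -0.22), and r4 to r7 gave 0, with 10807 of 56369 bins at an unadjusted p under 0.05 (edgeR, the only tool run there). Without H3K9me2 r6, r8 or r9 the count fell to 6840, 6458 or 6050.

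**Figure D2:**
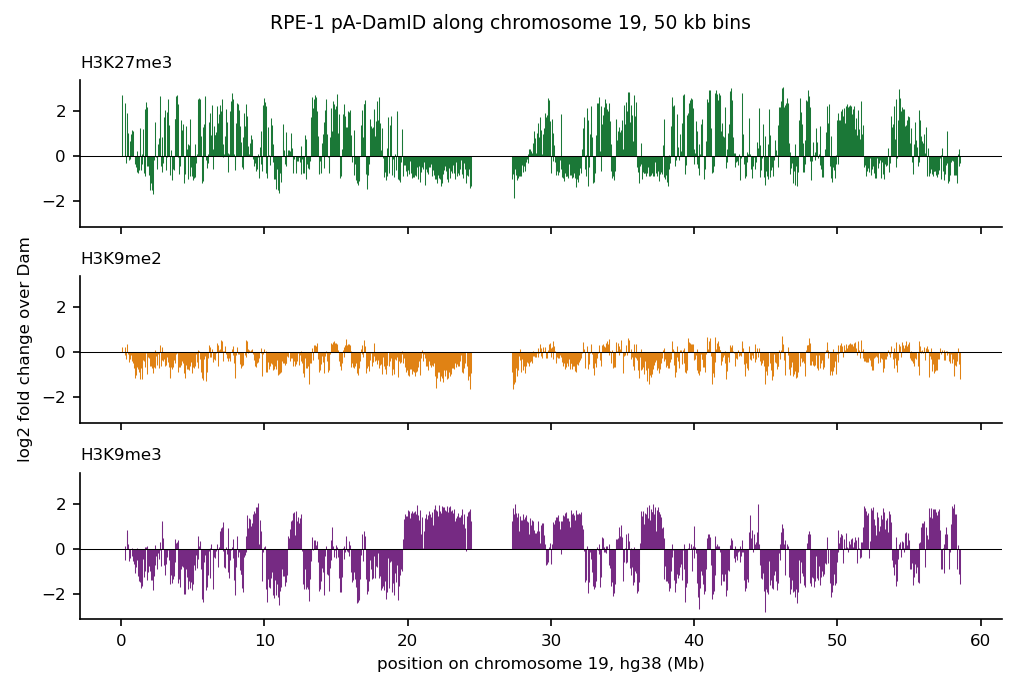
Log2 fold change over Dam (y axis, TMM-scaled) of H3K27me3, H3K9me2 and H3K9me3 in 50 kb bins (vertical lines) along chromosome 19 of RPE-1 cells (x axis, Mb, hg38); gaps are bins without a value. H3K9me3 forms blocks of positive bins, among them the zinc finger cluster at 20 to 24 Mb, where H3K27me3 is mostly negative; H3K27me3 has a block at 50 to 52 Mb, and the sign of weak bins moves with the scaling (47.9% of called H3K27me3 bins higher genome-wide, 24.7% under library totals).

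In K562 cells, PCI-24781 was compared with DMSO to see where deacetylase inhibition changes H3K27ac, a mark of active promoters and enhancers. Sites gained and sites lost both lay mostly away from gene ends. The gene ends gained included BBC3, which encodes the pro-apoptotic protein PUMA, and CAV1, the caveolin gene. Losses were fewer than another split of the lists gave, but lost regions were more once peak numbers were equal. The lists held 49537 ± 2261 peaks with PCI-24781 and 40124 ± 873 with DMSO (SD, n = 3 each), a difference of 9412.67 (SE 1399.63; differences between single lists 6284 to 12211; exact permutation p = 0.10, the smallest that 3 against 3 allows). Over all 3 treatments the exact permutation p of the F statistic was 0.0107, 0.0762 after adjustment over 16 measures, 0.05 without PCI-24781 replicate 1 and 0.0536 without replicate 2. All 3 PCI-24781 lists and none of the DMSO lists held 1575 of 71118 regions, and 179 showed the reverse; among the 9 other splits of these lists, at most 466 changed in one direction. Of the gained regions 9.27% lay at a gene end, 42.6% in a gene body and 48.1% between genes, against 18.7%, 45.7% and 35.6% of all 71118 regions and 41.9%, 31.1% and 27.03% of the 23362 regions found in all 9 lists. The last are wider. Of the lost regions 8.38% lay at a gene end. The stretches covered by all 3 DMSO H3K27me3 lists were touched by 3.05% of the gained regions, 0% of the lost, 1.12% of all regions and 0.30% of the common ones. With tubastatin A 2.32% of gained and 0.57% of lost regions touched them. Gained regions lack H3K27ac in DMSO by selection, so these shares do not measure an effect of the drug. Of all H3K27ac peaks 0.651% ± 0.117 touched them with PCI-24781 against 0.313% ± 0.0603 with DMSO (exact permutation F p = 0.0107, adjusted 0.0762). H3K27ac was gained at 99 genes and lost at 9, with at most 18 in one direction in another split. Ranked by strength in their lists, the gained were BBC3 (chromosome 19, 47220824 to 47232860), MSMB, GPR84, PLB1, LIN28A, PCDH1, ZNF892, CAV1 and PKDCC; at BBC3 a neighbouring peak had widened. Of the 73 gene calls named for either mark and drug, 3 stayed with windows at least 50% covered (PCDH1 here, PLB1 with tubastatin A, and MFSD11 for H3K27me3) and 26, all for H3K27ac, with a -log10 q of at least 5. BBC3 and CAV1 were among those lost at 50% coverage, and TERT under both. The lost were PPM1L, PAQR9, CFAP95, PGF, CDK3, SCART1, TERT (chromosome 5, 1253167 to 1295068), PRR5-ARHGAP8 and ZNF763. With the same number of peaks in each list, 744 regions were gained and 425 lost (at most 264 in one direction in another split), and 63 genes gained and 11 lost (16).

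Tubastatin A was compared with DMSO to ask the same of an HDAC6 inhibitor. Fewer sites changed. CAV1 and the phospholipase gene PLB1 were among the genes gained, and losses were again fewer than another split gave, but for lost regions at equal peak numbers. The lists held 43143 ± 3553 H3K27ac peaks, 3018.67 more than DMSO (differences between single lists -1552 to 6868; exact permutation p = 0.3). Gained regions numbered 560 and lost 174, with at most 339 changed in one direction in another split, and 41 genes were gained and 5 lost (26). With equal peak numbers 400 regions were gained and 248 lost (227), and 33 genes gained and 8 lost (21). The named gained genes were IGSF9 (chromosome 1, 159927041 to 159945613), TSGA10IP, PLB1, MOGAT3, FBXL2, DOK4, CAV1, OTUD7A, HIP1R and NAT8L, and the lost were DISP3, HEYL, RNF225, CLDN6 and ACP4. Both drugs gained 249 regions and 20 genes in common. Independent changes would share 12.4 and 0.33. Calls shuffled over the lists of DMSO and both drugs shared a median of 27 regions (highest 40) and 2 genes (highest 6). The shuffle does not keep each drug's number of changes. It therefore cannot tell how much of the overlap comes from the DMSO lists that both comparisons use. PCI-24781 lists held 6394 more peaks than tubastatin A lists (1008 to 12171 between single lists; exact permutation p = 0.10, the smallest possible), and 732 regions were gained and 194 lost between them, fewer than the 1122 changed in another split. By overlap in base pairs, lists of the same treatment shared a Jaccard index of 0.706 and lists of different treatments 0.677 (R² 35.2%, exact permutation p = 0.0107).

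**Figure D3:**
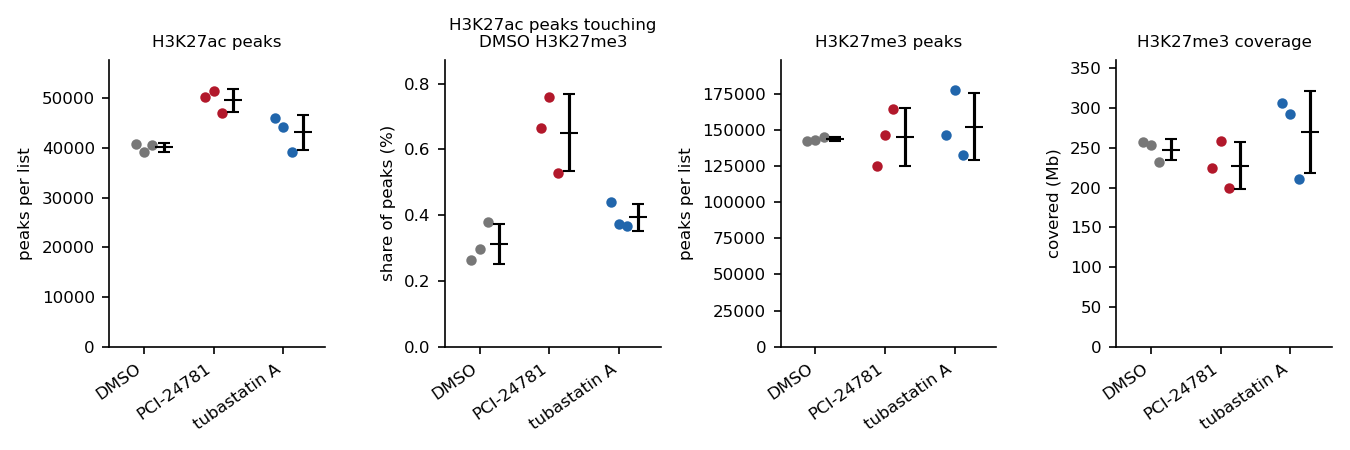
Each point is a peak list of K562 cells, with the mean and SD of 3 lists beside it (black), for the number of H3K27ac peaks, the share of them touching H3K27me3 regions of DMSO cells (%), the number of H3K27me3 peaks and the length these cover (Mb). PCI-24781 lists lie above all DMSO lists for both H3K27ac measures (mean 49537 against 40124 peaks), while the H3K27me3 measures overlap between treatments.

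H3K27me3 was compared between the same treatments to see whether the Polycomb mark moves on deacetylase inhibition. With PCI-24781 more gene ends lost the mark than gained it, among them those of HOXC4, SIDT1 and the death-receptor gene TNFRSF21. Gains with PCI-24781 and losses of gene ends with tubastatin A did not exceed what another split of the lists gave, and gains of gene ends with tubastatin A did so only with unequal peak numbers. The genes named for these are calls without a test. Gained and lost regions with tubastatin A exceeded it only with equal peak numbers. Peaks numbered 143503 ± 1405 with DMSO, 145154 ± 19967 with PCI-24781 and 152268 ± 23089 with tubastatin A (SD, n = 3; exact permutation F p = 0.821). They covered 248 ± 13.7, 228 ± 29.4 and 270 ± 51.7 Mb (F p = 0.389, exact permutation; 0.0321 without tubastatin A replicate 3). Over all peaks, lists of a treatment resembled each other more than lists of different treatments, with a Jaccard index of 0.371 within and 0.346 between treatments (R² 29.4%, exact permutation p = 0.0036, the smallest the 9 lists allow; exact permutation p = 0.386 with only peaks of -log10 q at least 5). With PCI-24781, 977 of 310484 regions were gained and 1295 lost, where another split changed up to 995 in one direction. There 32 genes were gained and 85 lost (52 in another split). Equal peak numbers gave 767 and 1088 regions (898) and 27 and 81 genes (55). The lost were TNFRSF21 (chromosome 6, 47231532 to 47309905), TRNP1, CDC42EP5, TMEM109, EPCIP, SIDT1, HOXC4, DIO3, AMZ2 and PTPRT, and the gained AADACL4, RCOR2, FAM177B, ELOVL7, PDK1, PCDHGB7, CNGA4, SERPINA6, EEF1AKMT4 and GNG13. With tubastatin A, 1477 regions were gained and 836 lost (up to 1491 in one direction in another split). Genes numbered 58 gained and 40 lost (49), and with equal peak numbers 1038 and 890 regions (883) and 53 and 45 genes (60). The gained were SLC22A31, BOC, NOTCH4, DOP1B, TSEN15, PAMR1, ZNF547, PRPH2, OR51F2 and KCNN1, and the lost GOLGA6C, ZSCAN10, B4GALNT4, UQCRB, SALL3, PPP1R12B, MFSD11, GPIHBP1, DCHS1 and SLC52A3. Between the drugs 688 regions were higher with PCI-24781 and 1598 with tubastatin A (up to 1729 in another split). H3K27me3 peaks were weak, and a -log10 q of at least 5 left 30 to 96 of them per list.

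**Figure D4:**
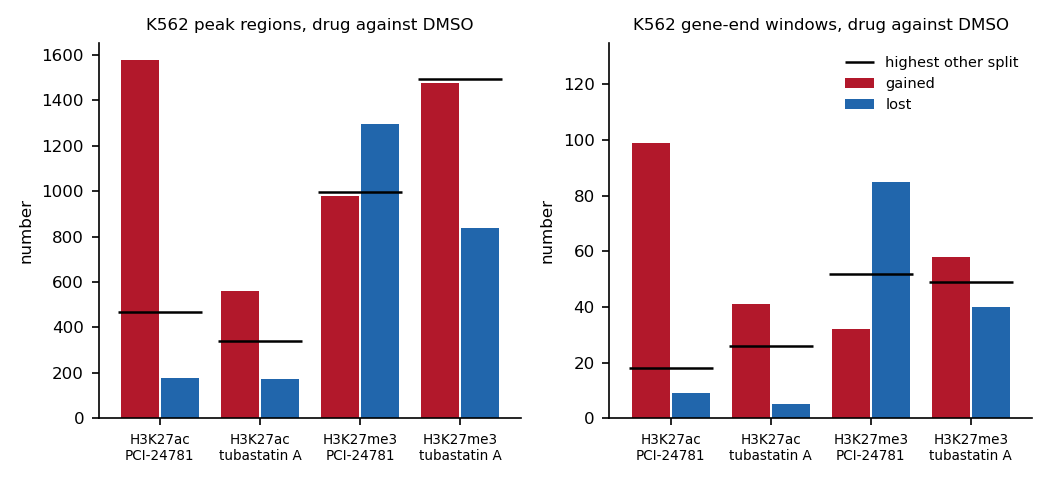
Bars give the number of K562 peak regions (left) and of genes with an end window (right) called in all 3 drug lists and no DMSO list (gained) or the reverse (lost), by mark and drug; black lines give the highest number changed in one direction in the 9 other splits of the same 6 lists. H3K27ac gains with PCI-24781 (1575 regions, 99 genes) stand far above that line, while H3K27me3 gains do not with PCI-24781 (977 against 995).

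Across the gene lists in K562, housekeeping (20 of 20), cell-cycle (24 of 24), ribosomal protein (81 of 83), repair (29 of 32), deacetylase and acetyltransferase (21 of 22) and erythroid genes (31 of 36) were marked by H3K27ac in equal number under every treatment. Genes that respond to deacetylase inhibitors were marked at 17.3 ± 0.577 of 27 with DMSO, 19.7 ± 0.577 with PCI-24781 and 18.3 ± 0.577 with tubastatin A (SD, n = 3; exact permutation p = 0.0214, adjusted 0.314 over 44 list tests). HOXC10, CAV1 and the meiosis gene STRA8 gained H3K27ac with both drugs, and GATA6, BBC3 and FN1 with PCI-24781. H3K27me3 lay on 26.7 ± 0.577, 24.3 ± 0.577 and 26 ± 0 of 39 HOX genes (exact permutation p = 0.0143, adjusted 0.314), on 96 ± 5.29, 89 ± 3 and 112 ± 5.51 of 387 olfactory receptors (exact permutation p = 0.0071, adjusted 0.314), and on 41 ± 6.93, 31 ± 1 and 35 ± 2.65 of 51 protocadherins (exact permutation p = 0.0607, adjusted 0.534). With PCI-24781 it was lost from HOXC4, ZNF625, the olfactory receptors OR6P1 and OR10A2, LRAT of the visual cycle, and PCDHA7, PCDHA8, PCDHA10 and PCDHA13. These PCDHA genes share a gene end, where the same peak can count for several of them. PCDHA7, PCDHA8 and PCDHA13 lost H3K27me3 with tubastatin A as well, and ZNF229, OR6C70 and PCDHGB7 gained it with PCI-24781. None of the 44 list tests passed after adjustment. Germline genes (11, 10 and 11.7 of 20) and developmental transcription factors (52.3, 49.3 and 49.7 of 66) carried H3K27me3 under all 3 treatments.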

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

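Of the tests in this part, the one with equal peak numbers, the splits of the peak lists and the comparison of peak ranks with other changed regions were chosen only after the result was seen. A library was singled out when its gap to the nearest other library exceeded the critical share of the group's range, which chance does in about 1 in 20 groups; 19 of 197 groups tested met this.

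The H3K27me3 r4 library resembled its group less than the others did, with a median correlation of 0.87 against 0.96 for the other 3 (gap 1 of the range). A mixture with H3K9me3 chromatin could produce this: over 13158 bins high in H3K9me3, r4 lay 0.69 above its group on the log2 scale and no other H3K27me3 library above -0.02. A higher share of Dam-type background would raise r4 over bins low in H3K27me3. There it lay 0.58 above, and no other H3K27me3 library above 0.01, as that explanation predicted. Across all bins, r4 correlated with the 6 Dam libraries at 0.52 to 0.59, and the other 3 H3K27me3 libraries at 0.70 to 0.81. This correlation was no part of the prediction. It argues against Dam-type background as the only source. It cannot exclude some of it, because H3K9me3 libraries correlated with Dam at -0.13 to 0.47 and a mixture with H3K9me3 chromatin would lower the value too. A property of all r4 libraries stays open, because Dam r4 rose by 0.21 over the H3K9me3-high bins, with Dam r6 at 0.15, while H3K9me3 r4 lay 0.62 above its own group there. No biological explanation was tested, because all RPE-1 libraries had the same treatment.

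H3K9me2 rarely rose far above the Dam control, with 6 bins more than 2-fold above it against 14602 for H3K9me3. More than 2-fold below Dam lay 1602 bins for H3K9me2 and 11933 for H3K9me3. The number and depth of the libraries do not account for the few bins above Dam. In 4 H3K9me3 libraries thinned to the H3K9me2 totals, 13919 bins still lay more than 2-fold above it. Bins below Dam were not counted in that test. A profile that does not repeat is excluded by a correlation of 0.82 across bins between the fold changes of r6 and r7 and those of r8 and r9 (Spearman 0.84; 85.7% of bins with the same sign), although both used Dam libraries of their own batch. A weaker enrichment by the antibody and a mark that is spread more evenly were not tested against each other and cannot be separated with these libraries. No biological explanation was tested.

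More H3K27ac regions were gained than lost with PCI-24781, 1575 against 179. More peaks in the PCI-24781 lists cannot be the whole reason, since with equal peak numbers 744 were gained and 425 lost, and at most 264 in one direction in another split. Peaks near the calling threshold cannot be told apart from the drug: 2.03% of the gained regions lay above the median rank in all 3 lists, but regions that no DMSO list calls are weak by selection, and the shares were 0.36% for gains with tubastatin A and 0.57% for its losses. The drug is the biological explanation that the design offers, and it stays open, as the ChIP depth is unknown.

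Dam r7 had 3.974% of its counts in its 1000 richest fragments, the other Dam libraries at most 1.124% (gap 0.885 of the range). Among named genes, Dam r7 stood above the other Dam libraries at HCFC1R1 (log2 CPM 7.54 against at most 5.56; 0.756), CCDC85B (6.97 against 5.66; 0.72) and EIF4A1 (6.11 against 4.64; 0.812). It stood below them at ZFP90 (4.16 against at least 5.03; 0.845) and ZNF501 (1.19 against 2.53; 0.713). Other Dam libraries stood apart at SIX6 (r6, 2.47 against at most 2.03; 0.657), TMEM106A (r4, 2.86 against at least 3.37; 0.654) and MEA1 (r5, 3.26 against 3.67; 0.641). H3K9me3 r4 had a median correlation of 0.775 with its group against 0.89 to 0.9 for the others (0.92). It held no count at SPAG5 (floor -0.89 against at least 2.4; 0.896) and at DEFB104A (-0.89 against 0.31; 0.759). H3K27me3 r4 was low at PROCA1 (0.44 against 1.44; 0.877), and H3K27me3 r5 at IFNA4 (3.13 against 4.22; 0.948) and SUCNR1 (0.54 against 1.58; 0.99). H3K9me2 r7 was low at INS (-0.89 against 1.02; 0.845) and ZNF891 (2.68 against 3.34; 0.943), and H3K9me2 r8 high at CCDC28B (4.53 against 4.18; 0.854). H3K27ac lists held peaks on sequences outside chromosomes 1 to 22 and X, which no comparison used, a mean of 101.7 with PCI-24781 (lowest list 97) against 75 to 87 with DMSO, while their share of all peaks was 0.205% against 0.2%.

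Regrouping the libraries at random tested whether chance could give as many calls. In each comparison 1 of the splits, the real one, reached its own count, so chance alone was unlikely to give it at that number of splits. Splits that mix antibodies widen the spread within groups, and the median of the other splits was 0 calls. The margin over them therefore does not measure the strength of a result. For genes, in fits of the 2 groups alone and 100 splits each, H3K27me3 against Dam had 12457 calls (highest other split 4147), H3K9me2 against Dam 7274 (1742), H3K9me3 against Dam 12927 (8532), H3K9me3 against H3K27me3 8519 (5053) and H3K9me2 against H3K9me3 7580 (3472). H3K9me2 against H3K27me3 had 10307 in 35 splits (0). For bins the counts were 38929 (19506), 19847 (1450) and 41856 (28780) for H3K27me3, H3K9me2 and H3K9me3 against Dam. Most of the highest other splits kept nearly all libraries of 1 antibody together. Where numbers pair the libraries, splits that part as many pairs as the real one gave at most 0 calls for H3K9me2 against Dam, H3K9me3 against Dam and H3K9me2 against H3K9me3. Such splits gave up to 3086 genes and 11049 bins for H3K27me3 against Dam, and up to 5053 genes for H3K9me3 against H3K27me3. In these comparisons same-numbered libraries did not all deviate together. For the peak lists of each drug against DMSO the real split ranked first of 10, too few for a share under 0.05. With PCI-24781 and tubastatin A, changed H3K27ac regions numbered 1754 and 734 (highest other split 585 and 453) and genes 108 and 46 (22 and 27). Changed H3K27me3 regions numbered 2272 and 2313 (1484 and 1854) and genes 117 and 98 (67 and 75).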

How the results depend on the processing

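Among the tests here, the windows around both gene ends were added only after the files had been seen, and the adjustment of list tests over all comparisons only after the results; the planned windows around the transcription start were not run as written, because the gene table gives no strand. Over all alternatives, 320 summary results stayed the same (counts within 1.5 times, tests with the same direction and side of 0.05), 139 counts moved, 16 became weaker, 3 stronger and 9 reversed. Of the values for single named genes in RPE-1, 10660 stayed the same, 415 became weaker, 202 stronger and 13 reversed, and in K562 545 stayed and 121 became weaker. The latter are 71 of 74 gene calls with windows at least 50% covered, 47 of 74 with a -log10 q of at least 5, and 3 with equal peak numbers. Gene counts stayed within 1.5 times under DESeq2, RLE factors, no low-count filter and fits of 2 groups. The cause was not tested except where stated.

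With the replicate block, H3K9me2 against Dam gave 9693 genes and 23689 bins. Only r8 and r9 gave 8404 genes and 22890 bins, and only r4 to r7 gave 0 genes and 0 bins. Only r4 to r7 also gave 6341 genes for H3K9me3 against H3K27me3, 6955 for H3K9me2 against H3K27me3 and 4712 for H3K9me2 against H3K9me3. Library totals gave 13008 genes for H3K9me2 against H3K9me3. The 2 groups alone gave 19847 H3K9me2 bins. Windows around both gene ends gave 3203 genes for H3K9me2 against Dam. Bins of 100 kb, fewer by construction, gave 22158 for H3K27me3, 6893 for H3K9me2 and 21824 for H3K9me3. An estimated correlation left 4 of 74 list calls, or 3 adjusted over all comparisons.

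Library totals reversed PCDHB8 (-0.04), HDAC8 (-0.31) and HDAC11 (-0.20) for H3K27me3 against Dam. For H3K9me3 against Dam they reversed RPL39L (-0.25), IL1RAPL1 (-0.12), GPC6 (-0.01), HDAC8 (-0.49), SUV39H1 (-0.19) and PGK1 (-0.45), and for H3K9me2 against H3K9me3 HDAC6 (0.02), TF (0.31) and TBP (0.01). Gene-end windows reversed GPC6 (-0.04) for H3K9me3 against H3K27me3.

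Peaks with a -log10 q of at least 5 left few H3K27me3 peaks. PCI-24781 minus tubastatin A then gave a difference of 4 peaks and PCI-24781 minus DMSO one of 0.02 Mb. Regions gained and lost were 0 and 1 with PCI-24781 and 2 and 1 with tubastatin A, genes 0 and 0 with either drug, and treatment took 25.12% of the distances (exact permutation p = 0.386). With equal peak numbers the share of H3K27ac peaks near gene ends was higher by 1.92 (PCI-24781) and 0.39 (tubastatin A) percentage points instead of lower. H3K27ac regions were then 744 gained and 425 lost with PCI-24781, with 63 genes gained, and tubastatin A lost 8 genes. With regions and windows at least 50% covered, H3K27ac genes lost were 25 (PCI-24781) and 19 (tubastatin A), and H3K27me3 regions gained and lost 248 and 674 (PCI-24781) and 758 and 327 (tubastatin A).

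Permuted within the replicate number, the H3K27ac peak differences of 9412.67 and 3018.67 (each drug minus DMSO) and 6394 (between drugs) and the shares in H3K27me3 (0.34 and 0.08) had an exact permutation p of 0.0556. Counting a change in most same-numbered pairs, a wider rule by construction, gave H3K27ac regions 7017 gained and 1270 lost (PCI-24781) and 3421 and 1527 (tubastatin A), and genes 438 and 51, and 199 and 58. H3K27me3 regions were 9402 and 11504, and 12965 and 9013, and genes 263 and 583, and 410 and 368.

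Leaving out each library in turn, H3K9me2 against Dam ranged from 2565 to 4564 genes and 6050 to 12575 bins. The H3K27ac peak difference was 8515.17 to 10682.67 for PCI-24781 against DMSO and 4403 to 7817 against tubastatin A. The covered length differed by 3.94 to 10.99 Mb between the drugs, and tubastatin A minus DMSO covered -2.29 to 4.75 Mb. For H3K27me3, peak differences ranged from -8059.5 to 11887 (PCI-24781), -3929 to 18637.5 (tubastatin A) and -16986.5 to 5580 (between drugs; 3122.33 without PCI-24781 replicate 1), and covered length from 3.85 to 51.61 Mb (tubastatin A) and -72 to -24.24 Mb (between drugs). With fewer lists required, counts rose: H3K27ac regions gained 2069 to 3900 and lost 273 to 486 (PCI-24781), and 771 to 1688 and 243 to 542 (tubastatin A), genes 118 to 208 and 12 to 23, and 50 to 90 and 10 to 22. H3K27me3 regions ranged from 1634 to 3761 and 2025 to 3976, and from 2413 to 5750 and 1163 to 2974, genes from 59 to 84 and 144 to 198, and from 90 to 141 and 64 to 107. Treatment took 43.58% to 51.05% of H3K27ac and 43.34% to 44.31% of H3K27me3 distances. The exact permutation p was 0.0667, the smallest that 6 lists allow, except for H3K27ac without replicate 2, where it was 0.333 and other groupings reached as much.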

Other observations

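In this part the simulations for the overlap of both drugs were chosen after the overlaps had been seen; the comparisons of marks were not in the design but were set, with their controls, before those overlaps were seen. Chromosomes differed in the share of bins above Dam. These shares were taken with TMM scaling alone, and the direction of bins moved with scaling, most of all for H3K9me2. H3K9me3 was higher on 57.3% of the bins of chromosome X, 51.4% of chromosome 21, 48.3% of chromosome 13 and 44.7% of chromosome 18, and on 20.9% of chromosome 17, 25.2% of chromosome 22 and 27.5% of chromosome 1. H3K27me3 was higher on 45.4% of chromosome X and 45.3% of chromosome 20, and on 26.8% of chromosome 13. H3K9me2 was lower on 36.6% of the bins of chromosome 21 and higher on 0.9% of chromosome 22 and 1.8% of chromosome 19.

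Marks shared bins unevenly. Of the 5512 bins higher in H3K9me2, 70.2% were also higher in H3K27me3, 3868 bins where independent lists would share 1860. With separate Dam libraries for each mark the count was 1945 where 1086 would be shared. H3K27me3 and H3K9me3 shared 5023 bins where 6986 would be shared by chance, 3071 and 5890 with separate Dam libraries. H3K9me2 and H3K9me3 shared 1372 and 2019, and 1050 and 2747 with separate Dam libraries. The main comparisons share their Dam libraries. All these sets rest on TMM scaling, and the direction of bins moved with it, most of all for H3K9me2. With separate Dam libraries the higher H3K9me2 bins numbered 3532 or 8104, by which Dam libraries were used. The shares of overlap were not computed under another scaling.

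In K562, the changes of both drugs overlapped for H3K27me3 too. They shared 170 gained regions, where independent changes would share 4.65 and shuffled calls gave a median of 84 (highest 108). Lost regions shared were 316, against 3.49 and a median of 216 (highest 247). The shuffle does not keep each drug's number of changes, so the part of the shared DMSO lists stays unknown. For H3K27ac 44 lost regions were shared (0.44; 46, highest 64) and 0 lost genes. Of the gene ends, 8 gained H3K27me3 with both drugs (0.22; 5, highest 12) and 14 lost it (0.41; 6, highest 14). Lost H3K27ac regions with PCI-24781 lay in gene bodies in 67.6% and between genes in 24.0%.

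H3K27me3 also differed among the remaining lists in RPE-1. Replication histone genes had a median of -0.58 against Dam, long neural genes -0.45 and cell-cycle genes -0.58, none past an adjusted p of 0.05 (camera), though long neural genes had an adjusted p of 0.0173 with the replicate block. Among cell-cycle genes CCND2 lay at 2.37 ± 0.19 and CCNA2 at -1.70 ± 0.44. Olfactory receptors had 149 of 366 higher and 31 lower (142 and 21 adjusted over the list alone), and their median of 0.31 turned to -0.38 under library totals (adjusted p = 0.0378, camera; adjusted p = 0.77 with an estimated correlation). In K562, H3K27ac lay on 7.33 ± 12.7 of 51 clustered protocadherins with DMSO, which came from 1 of its 3 lists, on 0.333 ± 0.577 with PCI-24781 and on 0 with tubastatin A (exact permutation p = 1).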
